A study of Mus musculus with 6 samples.

How the data were processed

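Gene expression was measured on Affymetrix mouse gene arrays, 1 array per sample. Group 3 innate lymphoid cells (ILC3s) bearing the chemokine receptor CCR6 were isolated from small intestinal lamina propria of C57BL/6 mice by collagenase IV digestion and cell sorting, per the labels' protocols. Total RNA was purified with a column micro kit and 2 ng was amplified with a NuGEN whole-transcript kit for small inputs before biotin labelling, per the labels' protocols. The control group holds 3 samples from mice with floxed Tnfsf11 alleles, and the RANKL-deficient group holds 3 samples in which the same floxed alleles were combined with a Cre transgene. The control labels name no Cre, so Cre itself and the deletion are confounded. Tnfsf11 encodes RANKL. Groups and replicate numbers were taken from the sample titles.

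The values deposited by the authors are log2 expression values of 35556 probe sets on each of the 6 arrays. They were made with RMA in Affymetrix Expression Console, per the submitters' processing notes. Tool versions, exact settings, array annotation release and genome build are not given in the sources used here. The log2 scale was read from the range of the deposited values. RMA gives every array nearly the same distribution of probe intensities, so a shift of all genes in 1 group would not be seen. Amplification from 2 ng can widen the scatter of weakly expressed genes. The number of arrays limits the precision, since arrays give no read depth.

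Probe sets were named through the platform annotation, and symbols were updated by Entrez identifier against a RefSeq gene table of assembly GRCm38.p6. That table was used only for names and for which genes neighbour each other. Of the probe sets, 21789 had 1 symbol, 1621 had several and 12146 had none in the annotation table used here. Probe sets with several symbols or none were left out of the tests by gene, so genes sharing probe sets with near-identical copies are mostly absent. Of the 19938 genes tested, 19855 matched the reference by identifier and 83 kept the annotation's symbol. For the 999 genes with more than 1 probe set, the probe set with the highest mean over the 6 arrays was used. No filter on low values was applied. Some planned genes, and 1 of the planned lists, are not reported here.

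RANKL-deficient and control arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, trend and robust options off, no replicate block), two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Tnfsf11 was also compared by an exact two-sided permutation test. The labels do not say whether the samples of a group came from separate mice. The p-values by gene therefore measure the spread between these samples, which may be technical. Before the data were examined, 29 gene lists were fixed: cytokines, identity genes, pathways and markers of other cell types that the gate could hold. Each list needed 4 measured genes and was tested with limma's camera at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Members were also tested adjusted over the list alone. Camera compares the members with all other genes, so its direction is relative to them. At the preset correlation its p-value rests on the spread over genes, with degrees of freedom set by the number of genes. It is therefore no measure of the spread between arrays. With an estimated correlation, the degrees of freedom come from the arrays, so a call can be lost without a higher correlation. Each list was tested again by camera with an estimated correlation and on ranks, and by fry, which tests the members against no change rather than against other genes. In a comparison chosen after seeing the data, the mean difference of each list was also set against 10000 random lists of the same size, each member drawn from the 200 genes nearest in mean expression.

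The named genes were fixed by a rule before the data were examined. Tnfsf11 was always named. In each direction, 15 genes were to be taken with the largest difference among those past the adjusted threshold whose groups did not overlap. Missing places were filled with the smallest unadjusted p among genes with an absolute log2 difference of at least 0.5 and a mean above the median of all genes. Of each list, the 4 members with the smallest unadjusted p were named, and every measured effector cytokine.

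The procedure was tested on simulated data for the comparison of RANKL-deficient with control arrays, on 19938 genes of which 200 were changed. A log2 change of 1 was recovered in 0% of the changed genes. Recovery was 91.5% at a log2 change of 2, with 11 false calls, and 95% at 3, with 7 false calls. The simulated noise was independent between genes and held no array effects, and 200 planted changes ease the adjusted threshold. These shares can therefore overstate recovery in the real arrays, where Cd36 did not pass at a log2 difference of 4.20. A shift of the glycolysis list by 0.5 was recovered with 0 false lists in 1 simulated draw. Since the simulated genes varied independently, this does not measure how often lists of correlated genes pass falsely.

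The alternatives were a replicate block, quantile normalization, median centring, only genes above the median, the mean of all probe sets of a gene, array weights, leaving out each array in turn, eBayes with trend and robust options, an ordinary t-test, all probe sets, and the other list tests. Cyclic loess normalization and leaving out control arrays 1 and 2 together were added after seeing the data. Tables and figures were made with pandas 2.3.3 and matplotlib 3.10.9 in Python 3.11.15.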

Results

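The data are whole-transcript expression profiles of CCR6+ ILC3s from the small intestine. Of the arrays, 3 came from control mice and 3 from mice with floxed Tnfsf11 alleles and a Cre transgene, here called RANKL-deficient. ILC3s are innate lymphocytes that make cytokines of the IL-17 family and help maintain the gut barrier. CCR6 marks the subset related to lymphoid tissue inducer (LTi) cells. RANKL is a membrane-bound and secreted cytokine of the TNF superfamily that signals through the receptor RANK. The comparison asks which transcripts of these cells differ between the groups. The labels of the RANKL-deficient group name a Cre transgene and those of the control group do not, so an effect of Cre itself is not separated from that of the deletion.

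The arrays had closely matched medians, from 5.07 to 5.15 on the log2 scale, but 2 control arrays stood apart. Control array 1 had the narrowest spread of values (SD 1.86 over genes) and the lowest mean correlation with the other arrays (0.960 across genes). Control array 2 followed, with an SD of 1.93 and a mean correlation of 0.970. The other 4 arrays had SDs of 1.99 to 2.01 and mean correlations of 0.975 to 0.977. On control array 1, 247 genes lay more than 1.5 log2 units below the median of the other 5 arrays, against 75 on control array 2 and 11 to 28 on the rest. The first principal component (39.3% of the variance) set control array 1 apart, and the second (22.3%) control array 2. The control arrays did not group together. Control array 3 correlated more with the RANKL-deficient arrays (0.981 to 0.983) than with control array 1 (0.962) or 2 (0.976). On the first component it scored 10.8, nearest the RANKL-deficient arrays (16.6 to 19.9). Its estimated array weight was 0.60, against 0.45 for control array 1 and 1.32 to 1.47 for the rest. The median difference of all genes, RANKL-deficient minus control, was −0.054. With genes placed in 4 equal bins by mean expression, it ran from −0.10 in the lowest bin to 0.080 in the highest.

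Tnfsf11 itself measured alike in both groups. Its log2 value was 8.47 ± 0.26 (SD, n = 3) in control and 8.51 ± 0.15 (SD, n = 3) in RANKL-deficient cells. The difference was 0.035 with a 95% confidence interval of −0.37 to 0.44 (limma, adjusted p = 0.963). An exact two-sided permutation test gave p = 1, where 3 arrays against 3 cannot go below 0.1. Its single probe set (10421737) has no stated position relative to the floxed exons, so this value does not check the labels. The sign of the difference turned under some scalings, to −0.033 after quantile normalization. The receptor gene Tnfrsf11a, named after its values were seen, measured 6.84 ± 0.33 in control and 6.92 ± 0.16 in RANKL-deficient cells.

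Ccr2 was the 1 gene past the adjusted threshold, and it rose in RANKL-deficient cells. It encodes the receptor for the chemokine CCL2 and is best known from inflammatory monocytes. Its log2 value was 5.03 ± 0.14 (SD, n = 3) in control and 7.79 ± 0.31 (SD, n = 3) in RANKL-deficient cells, a 6.78-fold difference (log2 2.76, SE 0.18, limma adjusted p = 0.0236). All 3 RANKL-deficient arrays (7.44 to 7.98) lay above all 3 control arrays (4.89 to 5.15). The control mean lay below the median of all genes (5.12) and no background level was measured here, so the fold would be a lower bound if control cells were at background. The same limit holds for any gene with a group mean below that median. The call was lost when any 1 array other than RANKL-deficient array 3 was left out (adjusted p from 0.0673 without control array 1 to 0.250 without RANKL-deficient array 2), while the log2 difference stayed between 2.67 and 2.94. It was also lost with the replicate block (adjusted p = 0.331) and without control arrays 1 and 2 (adjusted p = 0.461), and 0 genes passed when all probe sets were tested. No gene passed in the lower direction. At an unadjusted p under 0.05 there were 1624 genes, 847 higher and 777 lower, where 996.9 are expected by chance. Regrouping the same arrays into 3 and 3 gave 1119, 1120 and 1303 genes with control arrays 1 and 2 in the same group. The remaining regroupings gave 477 to 706 genes, so part of the excess over 996.9 may come from those control arrays. The 3 arrays of each group did not overlap for 14.4% of genes, against 10% by chance, a share not computed for the regroupings. Unlike the counts by p, most of these were lower, 1811 with all RANKL-deficient arrays below all control arrays and 1052 with all above.

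**Figure D1:**
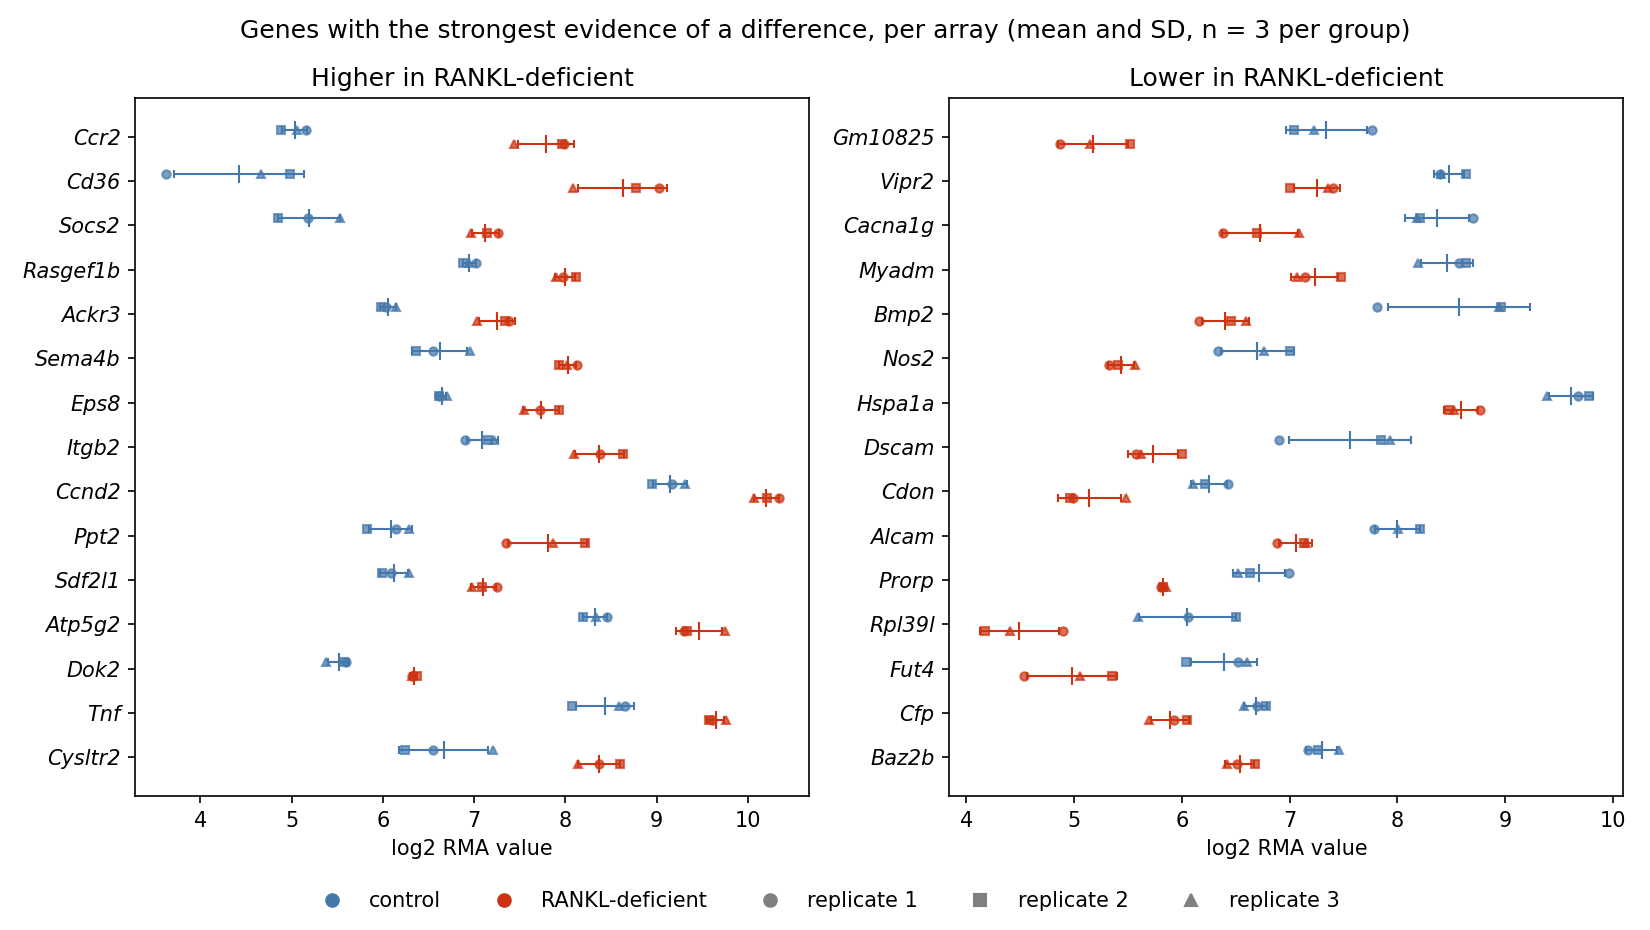
Log2 RMA value of each array (points), group mean (upright tick) and SD (error bar) for the named genes with the smallest p in each direction, control and RANKL-deficient, n = 3 each. Ccr2 went from a mean of 5.03 in control to 7.79 in RANKL-deficient cells and Cd36 from 4.42 to 8.63, with no overlap of arrays for either gene.

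The next genes by p in the higher direction did not pass the adjusted threshold, although their groups did not overlap. Cd36, a scavenger receptor that takes up long-chain fatty acids, had the largest difference among the named genes. It measured 4.42 ± 0.71 in control and 8.63 ± 0.49 in RANKL-deficient cells, 18.4-fold apart (log2 4.20, SE 0.39, adjusted p = 0.120). Its control mean also lay below the median gene, so the same limit holds for its fold. Cd36 passed together with Ccr2 only when eBayes was run with its trend and robust options. Socs2, a feedback inhibitor of cytokine signalling, differed by 1.93 (adjusted p = 0.135), but its other probe set gave 0.57. Ackr3, a scavenging receptor for CXCL12, differed by 1.20, and Cysltr2, a receptor for cysteinyl leukotrienes, by 1.70. Itgb2, the beta chain of the leukocyte integrins, differed by 1.28, and Ccnd2, a cyclin of G1 phase, by 1.06. The signalling adaptors Eps8 and Dok2 differed by 1.09 and 0.82, and the semaphorin Sema4b by 1.40. Rasgef1b, Ppt2 and Sdf2l1 differed by 1.05, 1.72 and 0.98. Atp5g2, a subunit of mitochondrial ATP synthase, differed by 1.14, and its 3 probe sets gave values from 1.00 to 1.26.

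In the lower direction, the named genes likewise missed the threshold, with adjusted p from 0.202 to 0.306. Bmp2, a secreted bone morphogenetic protein, measured 8.57 ± 0.66 in control and 6.40 ± 0.22 in RANKL-deficient cells (log2 −2.17, SE 0.32). The predicted gene Gm10825 had a log2 difference of −2.16. Vipr2, a receptor for the neuropeptide VIP, measured 8.48 ± 0.14 and 7.25 ± 0.22, a difference of −1.23. Nos2, the inducible nitric oxide synthase, differed by −1.27, and Cacna1g, a T-type calcium channel, by −1.64. The adhesion molecules Dscam and Alcam differed by −1.83 and −0.95, and the cell surface protein Cdon by −1.11. Fut4, a fucosyltransferase, differed by −1.40 and Cfp, the complement factor properdin, by −0.80. Myadm, Rpl39l, Prorp and Baz2b had differences of −1.23, −1.56, −0.89 and −0.76. The heat shock gene Hspa1a had −1.02 and is uncertain, since a near-identical copy exists.

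Of the 29 gene lists, 8 rose in RANKL-deficient cells relative to all other genes by camera with its preset correlation, and 0 fell. They were effector cytokines, chemokine and migration receptors, cell cycle, apoptosis and survival, immediate early genes, interferon response, glycolysis and oxidative phosphorylation. None of the 8 passed with an estimated correlation, where adjusted p lay between 0.160 and 0.266, and fry called 0 lists. The estimated correlation itself lay below the preset 0.01 for effector cytokines (−0.070), interferon response (−0.025) and glycolysis (−0.024). A higher correlation therefore did not remove these calls, and the few degrees of freedom from the arrays weigh in this test. Camera on ranks called 7 lists, which kept 6 of the 8 and added epithelial markers in the lower direction. Per array, the list means of the 2 groups did not overlap except for interferon response, where control array 2 (6.06) lay above RANKL-deficient array 1 (6.05). The control arrays that stood apart in the quality measures bear on these calls, and without control array 1 only cell cycle, apoptosis, chemokine receptors, glycolysis and oxidative phosphorylation passed.

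**Figure D2:**
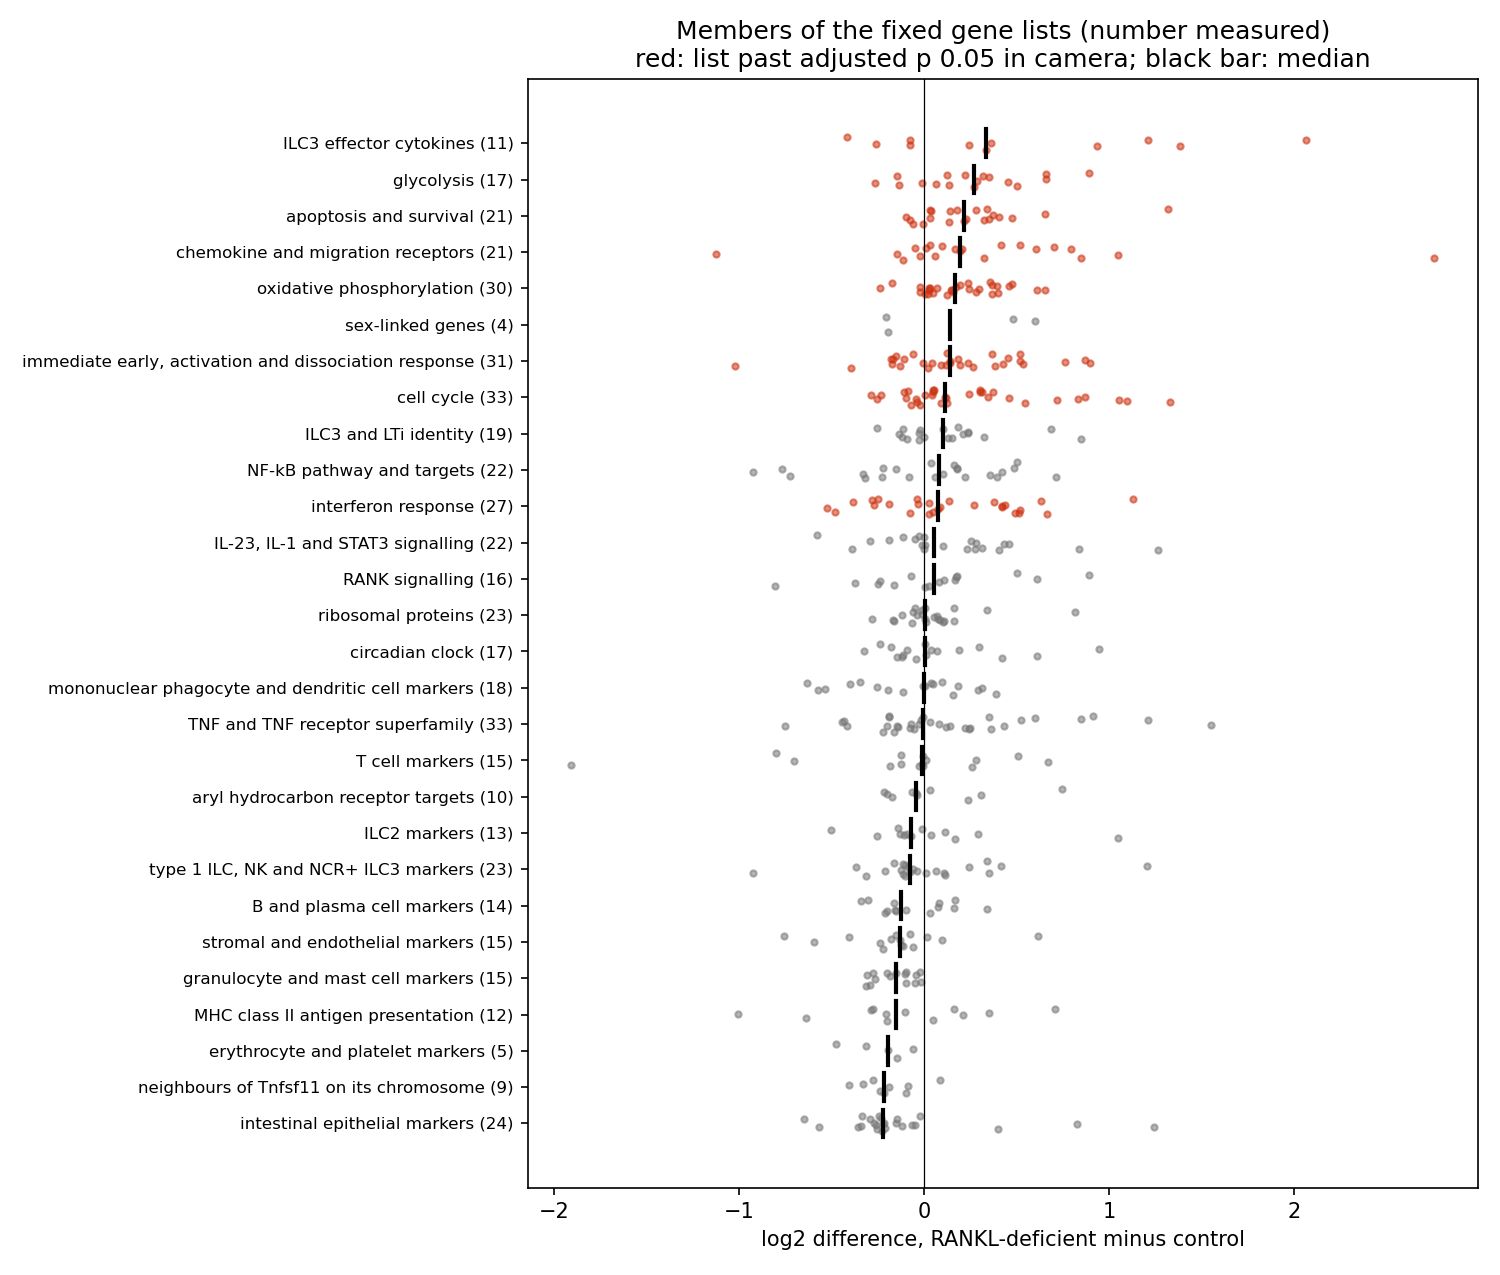
Log2 difference, RANKL-deficient minus control, of each measured member (points) of the fixed lists reported here, with the list median as a black bar and the number of measured members in brackets. Lists past adjusted p 0.05 in camera with preset correlation are red, and the medians of these 8 lists lie between 0.075 for interferon response and 0.34 for effector cytokines.

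The effector cytokine list rose (adjusted p = 0.00918 by camera, adjusted p = 0.192 with an estimated correlation), and 7 of 11 measured members had higher values. Adjusted over the list alone, 3 members passed, against 0 over all genes. Tnf measured 8.44 ± 0.32 in control and 9.65 ± 0.09 in RANKL-deficient cells (2.31-fold, list-alone adjusted p = 0.0030). Lif, an IL-6 family cytokine, measured 8.31 ± 1.20 and 10.38 ± 0.27 (4.19-fold, list-alone adjusted p = 0.0276). Its size depends on single arrays, with control array 2 at 9.64 and the other control arrays at 7.31 and 7.99, and the log2 difference of 2.07 ranged from 1.57 to 2.73 without 1 array. Il2, the T cell growth factor, measured 4.58 ± 0.31 and 5.97 ± 0.77 (2.61-fold, list-alone adjusted p = 0.0276), and since its control mean lay below the median gene, this fold too would be a lower bound if control cells were at background. The hallmark ILC3 cytokines Il17a and Il17f did not pass, with differences of 0.34 (SE 0.28) and −0.076 (SE 0.57). Without 1 array, these ranged from 0.034 (without control array 1) to 0.61 for Il17a and from −0.74 to 0.54 for Il17f. Il22 was not analysed here, since its probe sets carry several symbols. Csf2, which encodes GM-CSF, differed by 0.93 (SE 0.68), from 0.24 without control array 2 to 1.63 without control array 1. The lymphotoxin genes Lta and Ltb had differences of 0.36 and −0.42. Il10, Il21 and Ifng differed by 0.24, −0.26 and −0.077. The list's call was lost without control array 1 (adjusted p = 0.0512) and without control array 3 (adjusted p = 0.0644), while its mean difference of 0.52 stayed at 0.49 in both fits. It was also lost after cyclic loess (mean 0.50, adjusted p = 0.0678) and with camera on ranks (adjusted p = 0.0752).

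The chemokine and migration receptor list rose (adjusted p = 4.99e-05 by camera, adjusted p = 0.192 with an estimated correlation), with 16 of 21 members higher. Adjusted over the list alone, 5 members passed higher and 1 lower, and Ccr2 also passed over all genes. Ltb4r1, a receptor for leukotriene B4, differed by 0.70 (SE 0.14). Cxcr5, the receptor that guides cells to B cell follicles, measured 9.09 ± 0.27 in control and 9.94 ± 0.18 in RANKL-deficient cells, a difference of 0.85 (SE 0.18). The integrin chains Itgal and Itga4, named after their values were seen, differed by 0.60 and 0.79. Ccr9, the receptor for gut homing, was the 1 member that passed in the lower direction, at 6.18 ± 0.47 in control and 5.05 ± 0.37 in RANKL-deficient cells (log2 −1.12). Ccr6, the gating marker, measured 9.13 ± 0.62 and 9.45 ± 0.15.

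The cell cycle list rose (adjusted p = 0.000128 by camera, adjusted p = 0.160 with an estimated correlation), with 23 of 33 members higher. No member passed adjusted over the list alone. The replication helicase subunits Mcm4 and Mcm3 differed by 0.83 (SE 0.18) and 0.87 (SE 0.21). All 6 measured MCM helicase genes had higher values, with a median of 0.69, a subset chosen after the values were seen. Top2a, a topoisomerase of dividing cells, differed by 1.10 and its other probe set by 1.43. Stmn1, a microtubule regulator, differed by 1.33 and by 1.36 on its other probe set.

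The apoptosis and survival list rose (adjusted p = 0.000128 by camera, adjusted p = 0.192 with an estimated correlation), with 17 of 21 members higher. Its members act in opposite ways on cell death. The pro-apoptotic Bak1 measured 8.21 ± 0.49 in control and 9.54 ± 0.20 in RANKL-deficient cells and was the 1 member that passed adjusted over the list alone. The anti-apoptotic Bcl2l1 and Bcl2 differed by 0.66 and 0.33, and the pro-apoptotic Bik by 0.48. Without control arrays 1 and 2 together, the mean difference of the list went from 0.25 to 0.11 and the call was lost (adjusted p = 0.492).

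Immediate early, activation and dissociation genes rose as a list (adjusted p = 0.00101 by camera, adjusted p = 0.266 with an estimated correlation), with 21 of 31 members higher. Adjusted over the list alone, 4 members passed higher and 1, Hspa1a, lower. Fos, a subunit of the AP-1 transcription factor, measured 10.36 ± 0.04 in control and 10.88 ± 0.11 in RANKL-deficient cells. The early activation marker Cd69 differed by 0.54 and Zfp36, which destabilises cytokine mRNAs, by 0.45. Ier2, named after its values were seen, differed by 0.90. The 5 heat shock members had a median of −0.18 with 4 lower, while the 26 others had a median of 0.19 with 20 higher, a division made after the values were seen. The call was lost without control array 1 (adjusted p = 0.0729), after quantile normalization (adjusted p = 0.0836), among genes above the median (adjusted p = 0.130) and after cyclic loess (adjusted p = 0.148). Without control arrays 1 and 2 together, the mean difference went from 0.16 to 0.029 (adjusted p = 0.626).

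The interferon response list had the highest camera p of the 8 (adjusted p = 0.0373 by camera, adjusted p = 0.192 with an estimated correlation), with 17 of 27 members higher. Zbp1, a sensor of Z-form nucleic acids, differed by 0.63 and Psmb9, an immunoproteasome subunit, by 1.13, and both passed adjusted over the list alone. Oasl2 and the immunoproteasome subunit Psmb8 differed by 0.51 and 0.44 and did not pass. The call held in 5 of 17 alternatives, among them 2 of the 6 fits that left out 1 array, while the mean difference of 0.14 stayed between 0.10 and 0.20. It was lost without control array 1 (adjusted p = 0.111), control array 3 (0.0604), RANKL-deficient array 2 (0.0719) or RANKL-deficient array 3 (0.104), and without control arrays 1 and 2 together (0.244). It was also lost with quantile normalization (0.106), only genes above the median (0.229), array weights (0.0531), cyclic loess (0.148) and camera on ranks (0.0751).

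The energy metabolism lists rose with small differences per gene. Glycolysis had 13 of 17 members higher and a median of 0.27 (adjusted p = 0.00110 by camera, adjusted p = 0.160 with an estimated correlation). Hk2 and Pfkl, enzymes of early glycolysis, differed by 0.89 and 0.66. The glucose transporter Slc2a3 differed by 0.66 and Ldha, which makes lactate, by 0.50. Oxidative phosphorylation had 26 of 30 members higher and a median of 0.17 (adjusted p = 4.99e-05 by camera, adjusted p = 0.160 with an estimated correlation). Sdhb, Cox4i1, Cox5a and Atp5c1, subunits of respiratory complexes and ATP synthase, differed by 0.66, 0.61, 0.37 and 0.36. No member of either list passed adjusted over the list alone. After cyclic loess normalization, chosen after seeing the data, glycolysis had a mean difference of 0.21 against 0.26 and lost its call (adjusted p = 0.0799). Oxidative phosphorylation went from 0.20 to 0.11 and lost its call too (adjusted p = 0.135).

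**Figure D3:**
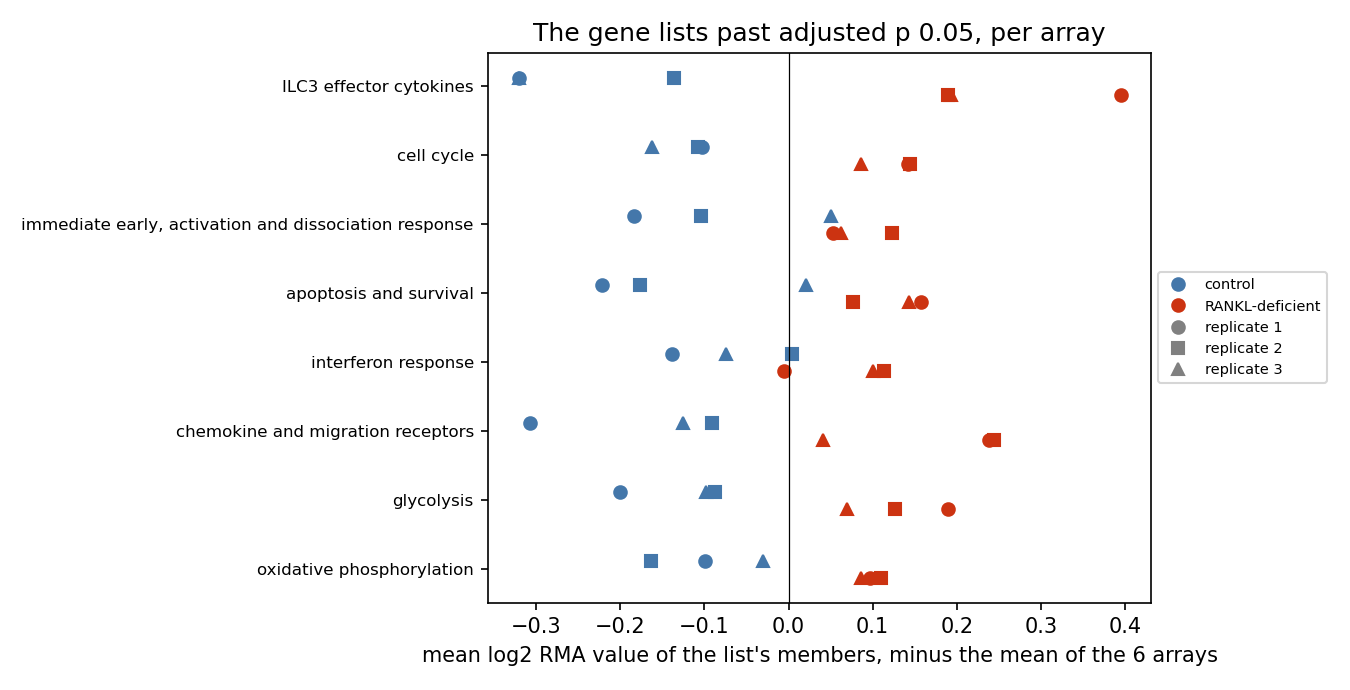
Mean log2 RMA value of the members of each of the 8 lists on each array, minus the mean of the 6 arrays, for control and RANKL-deficient arrays (n = 3 each). The oxidative phosphorylation mean was 8.96 to 9.09 on the control arrays and 9.20 to 9.23 on the RANKL-deficient arrays, and the groups overlapped only in interferon response.

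Genes that define the ILC3 and LTi lineage did not pass as a list (19 measured, median 0.10, adjusted p = 0.0526). The list passed higher with median centring (adjusted p = 0.0422), with the replicate block (0.0468), and without RANKL-deficient array 1 (0.0428), control array 2 (0.0394) or control array 3 (0.00971). Its mean difference of 0.12 went to 0.027 with cyclic loess (adjusted p = 0.908) and to −0.0068 without control arrays 1 and 2 (adjusted p = 0.972), where its direction turned. Cxcr5 passed adjusted over the list alone, and Cd4, carried by many LTi cells, measured 8.63 ± 0.39 in control and 9.32 ± 0.16 in RANKL-deficient cells without passing. The transcription factor Maf differed by 0.24 and Il2ra, the alpha chain of the IL-2 receptor, by 0.18. Il7r and Il23r, cytokine receptors of ILC3s named after their values were seen, had high values in both groups, 12.28 and 12.26 for Il7r and 10.70 and 10.80 for Il23r. The list of IL-23, IL-1 and STAT3 signalling genes did not pass (22 measured, median 0.056, adjusted p = 0.0723), except without control array 2 (adjusted p = 0.0234). Among them, Il12rb1, the shared receptor chain for IL-12 and IL-23, differed by 1.26 (SE 0.37) and the kinase gene Pim2 by 0.84. Il6ra and Socs1 differed by −0.39 and 0.43.

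Signalling lists downstream of RANKL and its relatives did not pass. RANK signalling had 10 of 16 members higher and a median of 0.053 (adjusted p = 0.737). Its kinase Src and adaptor Gab2 differed by −0.81 and −0.37, and Lgr4, a further RANKL receptor, by 0.50. The ubiquitin ligase Traf6 differed by 0.89 (SE 0.37), with control array 1 at 4.82 and the other control arrays at 6.30 and 6.15. The NF-kB list did not pass (22 measured, median 0.082, adjusted p = 0.648), but 2 members passed lower adjusted over the list alone. Nfkb2, the p100 precursor of the alternative pathway, measured 8.70 ± 0.10 in control and 7.93 ± 0.29 in RANKL-deficient cells. Tnip1, an inhibitor of NF-kB signalling, measured 7.79 ± 0.20 and 7.07 ± 0.15. Birc2 and Nfkbid differed by 0.50 and 0.72, though the other probe set of Birc2 gave 0.15. The TNF and TNF receptor superfamily (33 measured, adjusted p = 0.0723) had a mean of 0.13 and a median of −0.0057, which differ in sign, and it passed without RANKL-deficient array 2 (adjusted p = 0.0397). Of its members, Tnf passed adjusted over the list alone. Tnfrsf18, which encodes GITR, differed by 1.55 (SE 0.43), Tnfsf8 by 0.85 and Tnfrsf8 by −0.44.

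MHC class II antigen presentation did not pass (12 measured, median −0.15, adjusted p = 0.690). Cd74, the invariant chain, measured 10.14 ± 0.37 in control and 9.13 ± 0.63 in RANKL-deficient cells, and H2-Oa and H2-Ob differed by −0.64 and −0.27. Ifi30, a lysosomal thiol reductase, differed by 0.71. Aryl hydrocarbon receptor targets did not pass either (10 measured, adjusted p = 0.525), with a mean of 0.059 and a median of −0.042, which differ in sign. The partner gene Arnt differed by 0.75, Tiparp by 0.31, Ahr by 0.24 and Nfe2l2 by −0.20. Ribosomal protein genes had a median of 0.0043 (23 measured, adjusted p = 0.229). Rps2 passed adjusted over that list alone at 0.82, but its other probe sets gave 0.11 and 0.57. Rps3, Rps19 and Rpl24 differed by 0.34, −0.28 and 0.16.

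Markers of other lymphocytes that a CCR6+ ILC3 gate could hold did not pass as lists. T cell markers (15 measured, adjusted p = 0.932) had a mean of −0.14 and a median of −0.0098, while camera's direction was up. Cd3g passed lower adjusted over the list alone, at 6.69 ± 0.78 in control and 4.78 ± 0.54 in RANKL-deficient cells (log2 −1.91, SE 0.43). The other CD3 chains, Cd3e and Cd3d, named after their values were seen, differed by −0.70 and 0.26. Lat, Icos and Trat1 differed by 0.51, 0.67 and 0.28, where Icos had control array 1 at 9.51 and the other control arrays at 10.59 and 10.22. Type 1 ILC and NK markers (23 measured, adjusted p = 0.528) had a mean of 0.0021 and a median of −0.077. Klrk1, the activating receptor NKG2D, passed adjusted over the list alone at 7.50 ± 0.27 in control and 8.70 ± 0.26 in RANKL-deficient cells. Ncr1, the NKp46 receptor, measured 4.70 ± 0.77 and 3.77 ± 0.14, and Gzmc and Eomes differed by 0.35 and −0.31. ILC2 markers (13 measured, adjusted p = 0.802) had a mean of 0.027 and a median of −0.073. Their members Ccr8, Arg1, Pparg and Klrg1 differed by 1.05, 0.29, −0.25 and −0.50. Single arrays weigh on Ccr8 (control array 1 at 4.26, the other control arrays at 5.34 and 5.80). The same holds for Klrg1 (RANKL-deficient array 1 at 3.31, the others of that group at 4.36 and 4.80). B and plasma cell markers had a median of −0.12 (14 measured, adjusted p = 0.820), with Mzb1 at 0.34, Fcmr at −0.21, Fcrla at −0.20 and Ebf1 at −0.30.

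None of the 5 lists of non-lymphoid markers passed in the main camera test, on the deposited values with no replicate block. Epithelial and granulocyte markers did pass under some alternatives, given below. In 4 of the 5 lists, most members had lower values in RANKL-deficient cells. Mononuclear phagocyte and dendritic cell markers had 9 of 18 members higher and a median of −0.0023 (adjusted p = 0.774). Ctss, Adgre1, Itgax and Cx3cr1 differed by −0.40, −0.54, 0.39 and 0.31. All 15 granulocyte and mast cell markers had lower values (median −0.15, adjusted p = 0.0664), among them Siglecf at −0.27, S100a8 at −0.31, Mcpt2 at −0.31 and Mpo at −0.29. Intestinal epithelial markers were lower for 21 of 24 members (median −0.22, adjusted p = 0.0664). Their members Olfm4, Lgals4 and Apob differed by −0.57, −0.65 and −0.21, and Reg3g by 0.83. Stromal and endothelial markers were lower for 12 of 15 members (median −0.13, adjusted p = 0.242), with Acta2 at −0.76, Vwf at −0.22, Pdgfrb at −0.59 and Sparc at 0.62. All 5 erythrocyte and platelet markers were lower (median −0.20, adjusted p = 0.0932), with Alas2 at −0.31, Itga2b at −0.20, Pf4 at −0.47 and Gp9 at −0.14. The size for Pf4 depends on control array 2, at 4.54 against 3.34 and 3.11 on the other control arrays. Genes in the lowest of the 4 expression bins had a median of −0.10 as a whole, and only 1 of the 15 granulocyte markers lay above the median gene. Epithelial markers passed lower with median centring (adjusted p = 0.0422), with the replicate block (0.0429), with camera on ranks (0.0453), and without RANKL-deficient array 2, where the mean went from −0.11 to −0.26 (0.00135). Granulocyte markers passed lower with the block (0.0468), without RANKL-deficient array 2 (0.0438) and without control array 3, where the mean went from −0.16 to −0.25 (0.0198). Without control arrays 1 and 2 together, the direction of the granulocyte list turned, with a mean of 0.0055 (adjusted p = 0.877).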

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

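Leaving out both control arrays 1 and 2, and cyclic loess normalization, were chosen after seeing the data. The count of 1 gene (Ccr2) was kept with quantile normalization, median centring, only genes above the median, the mean of all probe sets, array weights and cyclic loess. It was 2 with eBayes with trend and robust options (Ccr2 and Cd36), 0 with an ordinary t-test, 0 without control arrays 1 and 2, and 0 over all 35556 probe sets, where 2482 had an unadjusted p under 0.05. Leaving out 1 array gave 0 to 1 genes, with 1137 to 2812 genes at an unadjusted p under 0.05, and fewer arrays leave fewer degrees of freedom. The 8 lists became 3 with cyclic loess, 5 without control arrays 1 and 2, and 5 to 10 without 1 array. They became 0 with an estimated correlation, 0 with fry, and between 6 and 11 under the other alternatives. The labels do not say whether replicate numbers pair the samples. Deviations from the group means correlated at −0.023, 0.050 and 0.027 for same-numbered arrays and at −0.058 to 0.026 for the others. With 3 arrays per group, these values cannot settle the pairing. With the replicate block, 0 genes passed (1596 at an unadjusted p under 0.05), 11 lists passed and all 8 lists stayed past the threshold. The Tnfsf11 difference was −0.033 with quantile normalization, −0.058 with cyclic loess and −0.078 to 0.18 without 1 array, and its highest value was 0.26 without control arrays 1 and 2. The 14 alternatives that refit named genes gave 2056 values, since the fit with only genes above the median left out named genes below it. Of these values, 2033 kept direction and side of the threshold, 7 lost a call and 16 reversed. Only Ccr2 had a call, so all 7 losses were its own. For the other named genes, keeping the side meant only staying without a call. Of 490 values of lists, 398 kept direction and side of the threshold, 38 lost a call, 40 reversed and 14 gained a call. No scaling moved the median of all genes by over 0.1. Leaving out some 1 array made the difference of 45 of 149 named genes over 1.5 times larger or smaller, or reversed it.

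Among genes without a call, Ifng reversed to 0.028 with cyclic loess and 0.19 without control arrays 1 and 2, which also turned Mpo to 0.092, Sparc to −0.14, Pf4 to 0.079 and Nfe2l2 to 0.050. Without 1 array the ranges were −0.21 to 0.017 for Ifng, −0.12 to 0.43 for Il10, −0.74 to 0.54 for Il17f and −0.35 to 0.061 for Uty. In camera, a list's direction is set against all other genes, so it can turn while its mean difference keeps its sign. Fry tests a list against no change, so its direction can differ from camera's at the same mean. The directions that turned belonged to lists without a call, and the mean differences were as follows. T cell markers had −0.14 with the replicate block and with fry, −0.34 with only genes above the median, −0.18 with array weights and −0.22 to −0.089 without 1 array. NF-kB genes had −0.070 with quantile normalization, 0.0035 with only genes above the median and with fry, −0.063 with cyclic loess, −0.13 without control arrays 1 and 2, and −0.072 to 0.071 without 1 array. RANK signalling had 0.010 with quantile normalization, 0.026 with only genes above the median and with cyclic loess, −0.046 without control arrays 1 and 2, 0.053 with fry, and −0.027 to 0.10 without 1 array. Ribosomal proteins had −0.025 with quantile normalization, −0.057 with cyclic loess and −0.026 without control arrays 1 and 2. B and plasma cell markers had 0.080 with only genes above the median, −0.0053 with cyclic loess, −0.0060 without control arrays 1 and 2 and −0.080 to −0.043 without 1 array. Circadian genes had 0.035 with only genes above the median, 0.047 with cyclic loess and 0.016 to 0.15 without 1 array. ILC3 identity genes had 0.027 with cyclic loess and −0.0068 without control arrays 1 and 2, which also gave ILC2 markers −0.077 and granulocyte markers 0.0055. ILC2 markers had 0.027 with fry and −0.026 to 0.079 without 1 array. Without 1 array, type 1 markers ranged from −0.081 to 0.057, phagocyte markers from −0.16 to 0.059 and MHC class II genes from −0.17 to 0.015. The cause of these reversals was not tested.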

Other observations

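The phagocyte test, the comparison with expression-matched random lists, cyclic loess normalization and the joint removal of control arrays 1 and 2 were chosen after seeing the data.

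Lists of clock genes, sex-linked genes and chromosomal neighbours of Tnfsf11 did not pass camera. Clock genes had a median of 0.0039 (17 measured, adjusted p = 0.370). Within them, Hlf, a clock-controlled transcription factor, measured 7.09 ± 0.11 (SD, n = 3) in control and 7.70 ± 0.17 (SD, n = 3) in RANKL-deficient cells, and Per1 measured 8.56 ± 0.10 and 8.97 ± 0.16. Ciart differed by 0.95, its other probe set by 0.47, and Nr1d1 by −0.18. Neither these genes nor any other clock gene passed adjusted over the list alone. Sex-linked genes (4 measured, adjusted p = 0.285) had Kdm5d at 0.48, Eif2s3y at 0.60, Uty at −0.20 and Xist at −0.21. Over the 6 arrays, Xist measured 3.51 to 4.21, below the median of all genes (5.12). Kdm5d measured 6.36 to 7.13, Eif2s3y 6.94 to 8.34 and Uty 5.90 to 6.77, all above it. These levels do not separate the groups by sex. Of the 9 measured chromosomal neighbours of Tnfsf11, 8 had lower values (median −0.22, adjusted p = 0.0723), including Vwa8 at −0.22, Epsti1 at −0.24, Fam216b at −0.33 and Dnajc15 at −0.27.

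Set against random lists matched on mean expression, 4 of the 8 called lists lay above the central 95% of random means. Random members were drawn independently, so the percentiles ignore correlation between members and the spread between arrays. They use the same arrays as the calls and are no separate evidence for them. Effector cytokines stood at the 99.99th percentile, chemokine receptors at 99.98, cell cycle at 100 and apoptosis at 99.8. Glycolysis stood at 97.2, interferon response at 93.2, oxidative phosphorylation at 90.7 and immediate early genes at 86.0. Among lists that camera did not call, the TNF superfamily stood at 98.0, above that range, and ILC3 identity genes stood at 50.2. The neighbours of Tnfsf11 (mean −0.19, percentile 1.22) and stromal and endothelial markers (mean −0.15, percentile 2.26) lay below it.

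The first pattern is that 8 lists passed, all higher. Quality of control array 2 as the whole cause is argued against, since all 8 called lists still passed without that array. Quality of control array 1 stays open: 5 of the 8 passed without it, while of the other lists cytokines kept a mean difference of 0.49 of 0.52, and immediate early genes went from 0.16 to 0.11 and interferon response from 0.14 to 0.10. A narrower signal range of control arrays stays open, since 3 of the 8 still passed after cyclic loess. Of the lists that lost the call, mean differences went from 0.16 to 0.096 for immediate early genes and from 0.20 to 0.11 for oxidative phosphorylation. Glycolysis went from 0.26 to 0.21 and cytokines from 0.52 to 0.50, and interferon response stayed at 0.14. Cyclic loess also moved the median of all genes from −0.054 to −0.0017. Camera sets a list against the other genes, so these means alone do not decide for any of the lists. Of the 10 splits of the 6 arrays into 3 and 3, which are too few for a share under 0.05, 1 gave as many lists, the real one with 8, and the highest other gave 7, with control arrays 1 and 2 placed in the same group, so part of the count may come from those arrays and the genotype stays open beside them.

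The second pattern is the large difference of Ccr2 and Cd36. Mononuclear phagocytes carrying the listed markers, as the whole cause, are argued against, since the median difference of the 18 measured markers was −0.0023 with an SD of 0.32 over members. Of the 18, 11 lay above the median gene. The highest were Ctss, Apoe and C1qc, with means of 9.54, 8.86 and 7.65 over all arrays and differences of −0.40, −0.35 and 0.16. The list mixes several cell types, so a phagocyte with few of these markers is not covered. The largest rise among these markers was 0.39, for Itgax, against 2.76 for Ccr2 and 4.20 for Cd36. Quality of control arrays 1 and 2 is argued against too, since at least 90.5% of either difference was kept when either array or both were left out. Of the 10 splits, 1 gave as many genes past the threshold, the real one with 1, and the highest other gave 0, which is again too few splits for a share under 0.05. A hypothesis from these data is that the RANKL-deficient genotype may raise Ccr2 and Cd36 in cells sorted as CCR6+ ILC3s, which more samples would have to test. A shift in which lymphoid cells the gate held was not tested for this pattern. Whether the deletion or the Cre transgene would do so stays open, since only this group's labels name Cre.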
